A study of Drosophila melanogaster with 4 samples.

How the data were processed

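Heads of gabapentin-fed and control male flies were compared on 4 cDNA arrays with 2 colours, each with its own pair of RNA pools, per the labels. All 4 arrays form 1 group, gabapentin against normal food. Gabapentin RNA was labelled with Cy5 on arrays 1 and 2 and with Cy3 on arrays 3 and 4, and channel 1 is Cy5 on every array, per the labels. Each array pairs both conditions by construction, so the 4 arrays are the replicates of every test.

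The authors scanned the slides and quantified spots with GenePix Pro 6.0 and applied a ratio-based normalization in Acuity 4.0, per the series' design text. Per the same text, spots with a raw intensity under 100 units and under 2 times the background were ignored for normalization. Spots were kept with under 3% saturated pixels, no bad flag, a regression R2 of at least 0.6 between the channels and a signal-to-noise ratio of at least 3. The authors then ran SAM 2.21 as a one-class analysis with 100 permutations on spots analysable on at least 3 of 4 arrays, per the design text. No list of calls by the authors was used here. Most clones have no value after this filter, whose criteria were not separated here, and a gene without a value is not one without expression.

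The deposited values, 1 column per array, were taken as log2 ratios; the labels describe them only as normalized ratios. The log base is inferred from the values. The largest size in the table is 9.11, above 4.82, the most a 16-bit scan allows in log10, and above 6.49, the bound in natural logarithms with 1 channel at 100 units, but under the matching log2 bound of 9.36. Columns are not centred on 0, with medians of 1.14, 0.80, 0.52 and 0.78, and what the normalization centred on is not given in the sources used here. Direction stays unknown: whether the values of the dye-swapped arrays are Cy5 over Cy3 or were turned is not stated. The reading with arrays 3 and 4 turned was fixed as the main one, and the other reading was planned beside it. A turned array carries its positive offset with the opposite sign, so that offsets enter the spread of the uncentred test.

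Spots in rows that neighbour each other are duplicates: all 7558 pairs with symbols on both spots carry the same symbol. Their values were averaged to 13824 clones. Gene symbols came from the platform annotation, updated through Entrez IDs with the RefSeq table of assembly Release 6 plus ISO1 MT. Of 15116 spots with 1 symbol, 14894 were found there, and the others keep the annotation's symbol. In all 7558 clones have 1 symbol, 51 several and 6215 none, and only the first kind is named. No coordinates are given, since the sources name no build. All columns of per-array values were used.

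Clones with a value on at least 3 arrays were tested with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, Benjamini-Hochberg, threshold 0.05). The SE given for a clone is the one limma moderates over all clones, not the spread of its own arrays alone. Of the 668 clones on 3 arrays, 578 lack array 4, so a dye effect does not cancel in their means. Clones on all 4 arrays were also fitted with a common and an orientation coefficient. SAM was run as a one-class statistic with all 16 sign changes, with false calls taken as the median over them. A mean over sign changes, used at first, cannot give a q under 0.125 with 4 arrays and recovered no simulated change, so it was replaced after the first SAM counts had been seen. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Arrays were centred by subtracting the median over all clones with a value.

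Before the data were examined, 35 gene lists, the rule for named genes, the tests and a first set of other settings were fixed. Names were to be the 12 clones per direction with the largest mean past the threshold, a symbol, a value on all 4 arrays and the same sign on all, filled up by the lowest p where the mean was at least 0.3 in size. The same rule with 5 per direction applied to the other reading, and the tested calcium channel and GABA genes and 4 members of any list past the threshold were added. Lists with at least 5 measured genes were to be tested with camera on complete clones. Too few clones were complete, so cameraPR was run on the moderated statistics of clones on 3 or 4 arrays, with a preset correlation of 0.01, a choice made after seeing the data. An estimated correlation (camera) and fry were run on clones complete on arrays 1 to 3. Further settings of the second reading were run only for the 2 lists past the threshold there. The combination of centring with the second reading or with a further choice, SAM in the second reading, the tests within an orientation and the removal of a trend along the printing order by a running median were also chosen afterwards. The row order of the deposited values was taken as the printing order, which was not checked. In all, 34 settings of the clone counts were run over 4 combinations of reading and centring, and every value relative to the array median in the text comes from such a later or alternative setting, not from the uncentred main comparison. Further alternatives were scaling, robust moderation, array weights, other filters on missing values, gene averages and leaving out each replicate.

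The fits were tested on simulated data with the real pattern of missing values, offsets and array spreads and with changed clones of 2 sizes. Of 100 clones changed by 1 log2 unit, limma recovered 94% after centring with arrays turned (854 clones, 6 false calls), against 7% without centring. Of 100 changed by 2 units, it recovered 100% and 77%. SAM recovered 94% and 100% after centring. On arrays 1 and 2 alone 98% of changes of 1 unit were recovered over 1096 clones with 19 false calls, 8.76% of all calls. On arrays 3 and 4 alone 63.3% were recovered over 235 clones. In 100 draws, cameraPR gave p under 0.05 for 8 lists of 8 unchanged clones and for 100 lists shifted by 0.5. Simulated errors were independent between clones and between arrays, and 654 of the 854 clones were left unchanged. So large a changed share eases the adjusted threshold, and the rates may not hold where few clones change. In the real data, rg at 1.19 and nAChRalpha2 at 0.93 had a limma adjusted p of 0.374 after centring with arrays turned. A count of 0 there thus does not exclude changes of 1 unit. The correlation estimated on arrays 1 to 3, in the second reading after centring, was 0.294 for photoreceptor and 0.41 for ribosomal protein clones. The simulated rates therefore do not hold for lists of correlated genes such as these.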

Results

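Gene expression was measured in the heads of adult male fruit flies, Drosophila melanogaster of the Oregon-R wild type, after feeding with gabapentin. Gabapentin is an anticonvulsant and analgesic drug that binds the alpha2delta subunit of voltage-gated calcium channels in mammals. Unmated males aged 10 to 11 days were kept for 3 days in vials of 30 flies on food with 16 mg/ml gabapentin or on normal food. RNA from 4 pairs of head pools, each with a gabapentin and a normal food pool, was hybridised to 4 cDNA arrays with 2 colours, so that each array is 1 biological replicate. Gabapentin RNA carried Cy5 on arrays 1 and 2 and Cy3 on arrays 3 and 4. The question was which head transcripts differ in level between drug-fed and control flies.

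Few spots carried a value. Of 27648 spots, 3758 had a ratio on array 1, 4334 on array 2, 2750 on array 3 and 1333 on array 4. Neighbouring spots are duplicates of 1 cDNA clone, and their averages gave 13824 clones, of which 10255 had no value on any array. A value on 3 or 4 arrays was found for 854 clones, and 186 of these were measured on all 4. Among the 854 clones, 447 had 1 gene symbol and represented 427 genes, and 407 stay unnamed here. Duplicate spots correlated across clones at r = 0.47, 0.52, 0.82 and 0.63 on arrays 1 to 4, and the number of arrays limits the precision of every mean.

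**Figure D1:**
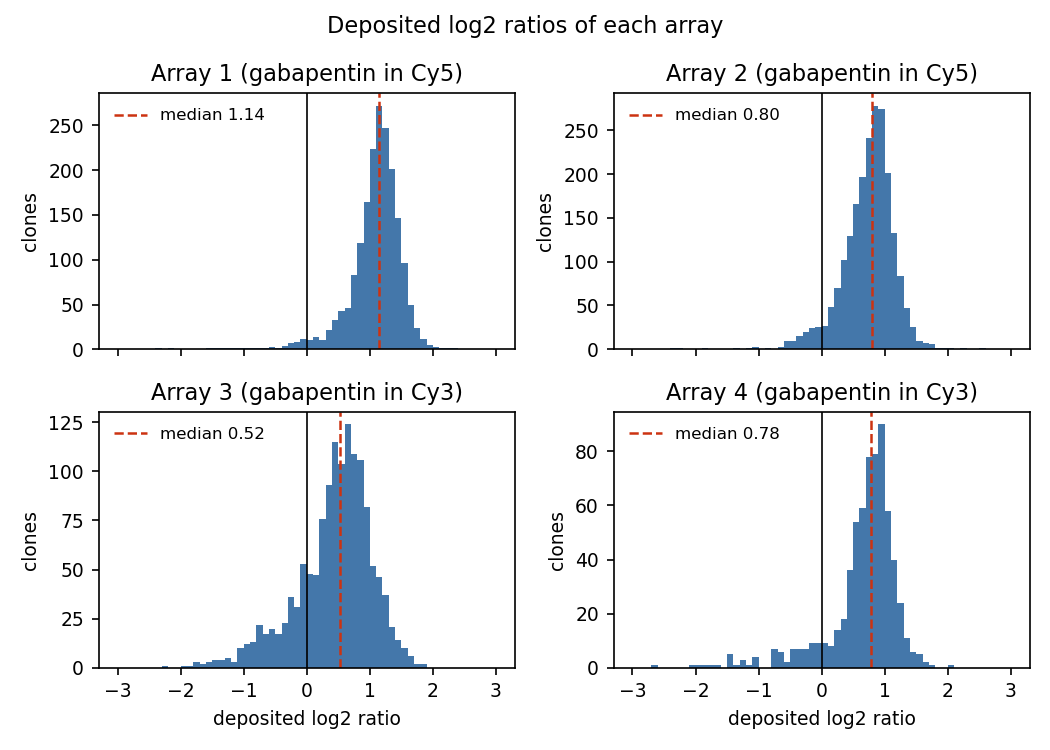
Histograms of the deposited log2 ratios per clone on each array, with the number of clones on the vertical axis, a black line at 0 and a dashed line at the median; 2, 1, 1 and 1 clones of arrays 1 to 4 lie outside the plotted range. All 4 medians lie above 0, at 1.14, 0.80, 0.52 and 0.78.

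Most measured transcripts shared 1 feature: their deposited ratio was above 0 on every array, whichever dye gabapentin carried. The median log2 ratio was 1.14, 0.80, 0.52 and 0.78 on arrays 1 to 4, and 97.3%, 94.5%, 79.5% and 88.8% of clones lay above 0. The labels do not state whether a value is Cy5 over Cy3 or was already turned to gabapentin over normal food on the dye-swapped arrays. Both readings were therefore computed, no direction is called settled, and changes of genes are given relative to each array's median unless stated otherwise. In the first reading, arrays 3 and 4 have their sign turned; in the second, all columns are used as deposited.

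No head transcript passed the test for a gabapentin effect in the comparison fixed before the data were examined. With arrays 3 and 4 turned and no centring, 0 of 854 clones were higher and 0 lower (limma, Benjamini-Hochberg adjusted p under 0.05), 0 had an unadjusted p under 0.05, and SAM called 0. The 95% interval of a clone extended a median of 1.21 log2 units to either side of its mean, since turned arrays then differ by their offsets. After centring each array, the count was again 0 higher and 0 lower, with 19 clones at an unadjusted p under 0.05 against 42.7 expected by chance and 0 SAM calls. The interval then extended a median of 0.39 log2 units, or 1.31-fold, to either side, and the smallest adjusted p was 0.374. No clone met the rule for names in this reading, which needed the same sign on all 4 arrays and a mean of at least 0.3 in size.

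Under the second reading without centring, 833 of the 854 clones were called higher with gabapentin and 0 lower by limma, and SAM called 796. The median of the 854 clones was 0.91 log2 units there and 0.09 after centring, when limma called 0 higher and 0 lower, the smallest adjusted p was 0.0922, and SAM called 0. Of the centred clones, 107 lay higher and 23 lower at an unadjusted p under 0.05, against 42.7 expected in all. That expectation takes 0 as the middle. Centring used all clones with a value, and the tested ones lay at 0.09, which tilts the counts to the higher side. The clones measured on all 4 arrays split the same way: 185 of 186 passed for the component common to the deposited columns and 0 for the component opposite between orientations, and after centring 0 passed for either in limma. At an unadjusted p under 0.05 there were then 43 clones for the common and 8 for the opposite component, with medians of 0.12 and -0.01.

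Genes of phototransduction and cytosolic ribosomal proteins lay above the array medians on arrays of both orientations. Of 8 tested photoreceptor clones, 7 had a positive mean in the second reading, with a list mean of 0.30 ± 0.26 (SD across clones). All 8 ribosomal protein clones were positive, with a list mean of 0.31 ± 0.11. Muscle markers had a mean of 0.37 and the glutamate list one of 0.29 in the same reading, with 3 of 3 clones positive in each. In a test on limma's moderated statistics with a preset correlation (cameraPR, 5 lists), the adjusted p after centring was 0.0186 for photoreceptor genes and 0.00881 for ribosomal proteins. It was 0.0136 and 0.0205 without centring. On ranks of these statistics, the cameraPR adjusted p after centring was 0.0509 and 0.0049, so the photoreceptor call was lost. Both calls are lost with an estimated correlation, taken on clones complete on arrays 1 to 3, at an adjusted p of 0.435 for each after centring, and 0.608 and 0.803 without it. In the first reading both lists had an adjusted p of 0.975, or 0.956 after centring.

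The photoreceptor list was led by genes of the light response. trp, which encodes the light-activated cation channel of the eye, lay 0.61 ± 0.16 log2 units (SE, n = 3 arrays) above the median, a 1.53-fold difference. inaD, the scaffold of the phototransduction complex, lay 0.51 ± 0.14 above it on 4 of 4 arrays. chp, the photoreceptor adhesion protein chaoptin, lay 0.48 ± 0.14 above it, and inaC, the eye protein kinase C, 0.29 ± 0.13, each on 4 of 4 arrays. The mean of inaC was 0.22 and 0.19 without replicate 1 or 2, and 0.35 and 0.38 without replicate 3 or 4. Arrays 1 and 2 thus carried most of it, and inaC hardly shows a shift in both orientations. Their adjusted p over all clones ran from 0.209 to 0.345 in limma, so none passed alone. Adjusted over the list alone, 3 of the 8 clones passed, against 0 in the list over all clones tested. Galphaq stood on the other side, at -0.22 ± 0.18. Over all clones of the list with a value on an array, tested or not, the medians were 0.11, 0.67, 0.59 and 0.10 on arrays 1 to 4 (11, 10, 8 and 5 clones). In the first reading the list mean was 0.02 ± 0.29 (SD), with 5 of 8 clones positive. The means of trp, inaD, chp and inaC were then 0.19, 0.19, 0.03 and 0.24, and those of Galphaq and of CG2233, also a list member, -0.22 and -0.52, all with an adjusted p of 0.999.

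Among the ribosomal proteins, RpL27 lay 0.47 ± 0.14 log2 units above the median (n = 3 arrays), RpL15 0.42 ± 0.15 (n = 3), RpL39 0.33 ± 0.13 (n = 4) and RpL17 0.27 ± 0.13 (n = 4). RpLP0, RpS7 and both clones of RpS15Ab were also positive. Adjusted over the list alone, 1 of 8 passed, and 0 over all clones tested. In the first reading 4 of the 8 clones were positive and the list mean was 0.00, with RpL39 at -0.13 and RpL15 at -0.06.

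The calls on both lists came from a test chosen after the data were seen, and they depend on how the correlation between genes is treated. Over the same clones on arrays 1 to 3, the adjusted p after centring was 0.00403 for each list with the preset correlation. fry, which tests a list against no change and not against the other clones, gave an adjusted p of 0.116 for each. Without replicate 2 or 3 the photoreceptor adjusted p was 0.263 or 0.367, and without replicate 1, 2 or 3 the ribosomal protein adjusted p was 0.404, 0.263 or 0.669, with fewer clones left to test.

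**Figure D2:**
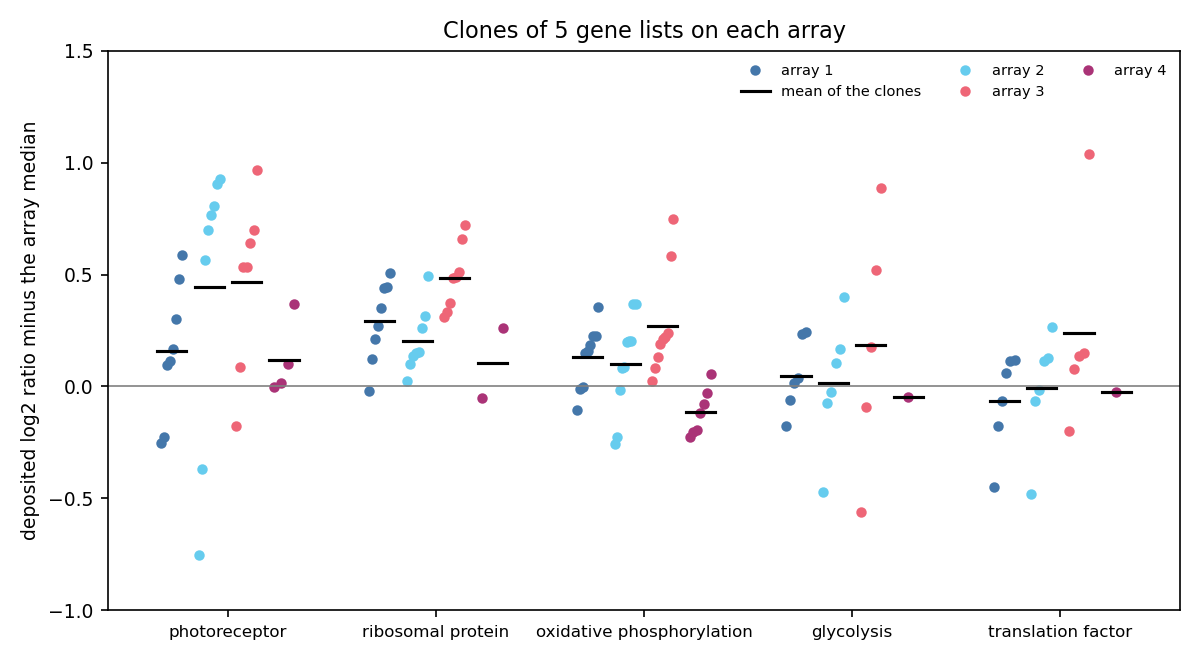
Deposited log2 ratio minus the array median (vertical axis) of each tested clone of 5 gene lists, by array (colour), with black bars for the mean over clones. Photoreceptor and ribosomal protein clones have means above 0 on all 4 arrays, whereas oxidative phosphorylation clones have a mean below 0 on array 4.

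Energy metabolism and translation factors stayed near the median. The 10 oxidative phosphorylation clones, which include ATP synthase and complex I subunits, had a mean of 0.10 ± 0.13 (SD) in the second reading after centring and 0.02 ± 0.06 in the first. The 6 glycolysis clones, among them Hex-A, Ald1, Tpi, Gapdh1, Pgk and Eno, had means of 0.07 ± 0.25 and -0.03 ± 0.17. The 6 translation factor clones had means of 0.04 ± 0.21 and -0.09 ± 0.17. The adjusted p of these 3 lists was 0.743 in the second reading and 0.956 in the first after centring, and 0.975 in the first without it. The test fixed beforehand for complete clones, camera on the 186 clones on all 4 arrays, could be run for oxidative phosphorylation alone (5 clones, limma adjusted p = 0.902).

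Genes of the drug's known target in mammals and of its namesake transmitter were barely measurable. Gad1, the glutamate decarboxylase that makes GABA, was the only tested member of the GABA list, with 0.18, 0.23, 0.37 and -0.38 relative to the medians of arrays 1 to 4. Its mean was 0.10 ± 0.16 (SE, n = 4, limma adjusted p = 0.999) in the first reading, with a 95% interval from -0.25 to 0.45 and means from 0.01 to 0.26 when 1 replicate was left out, and 0.10 ± 0.14 (adjusted p = 0.780) in the second. A second clone of Gad1 had no value. Gabat, the GABA transaminase, had values on 2 arrays, 0.22 on array 2 and -0.03 on array 4. Of the voltage-gated calcium channel list, 4 genes were on the array and none reached 3 arrays. Ca-beta had 0.12 on array 2 and -0.63 on array 3, and Ca-alpha1D had -0.04 on array 4. The clones of stj, an alpha2delta subunit, and of CG16868 had no value that passed the authors' filter. No difference of these genes was detectable with so few values.

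Single genes with the smallest p-values are named next, a choice made after their values were seen. In the first reading after centring, rg, an A-kinase anchor protein, stood at 1.19 ± 0.29 (SE, n = 3), nAChRalpha2, a nicotinic acetylcholine receptor subunit, at 0.93 ± 0.22, and Sidpn, a basic helix-loop-helix protein, at 0.77 ± 0.21. Scp1, a sarcoplasmic calcium-binding protein, stood at -0.96 ± 0.25. Their limma adjusted p was 0.374 to 0.414, so none passed. rg, nAChRalpha2 and Sidpn had no value on array 1, and in the second reading their means were -1.08, -0.76 and -0.62. As deposited, relative to the medians of arrays 2, 3 and 4, rg had 0.16, -1.21 and -2.20. nAChRalpha2 had 0.25, -1.29 and -1.24 there, and Sidpn 0.23, -0.92 and -1.17. Array 2 thus lay closest to its median for each, a spread that the moderated SE does not show in full. CG2233, CG16926, vig and CG4757 had means of -0.52, -0.46, -0.64 and -0.41, each with an adjusted p of 0.999. In the second reading the smallest adjusted p of named clones was 0.184, for vig at -0.82 ± 0.19 and CG16799 at 0.67 ± 0.16, and Obp56g stood at -0.81 ± 0.20. Other clones of vig and Obp56g gave -0.07 and 0.31, so clones of the same gene disagreed. The rule for names in the second reading took CG10553, inaD, chp, thoc7 and CG4716, all called without centring, with centred means of 0.52, 0.51, 0.48, 0.48 and 0.47. It took TP53INP at 0.41 as well after centring, when the adjusted p of all 6 ran from 0.209 to 0.246. Without replicate 3, CG4716 stood at 0.23.

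**Figure D3:**
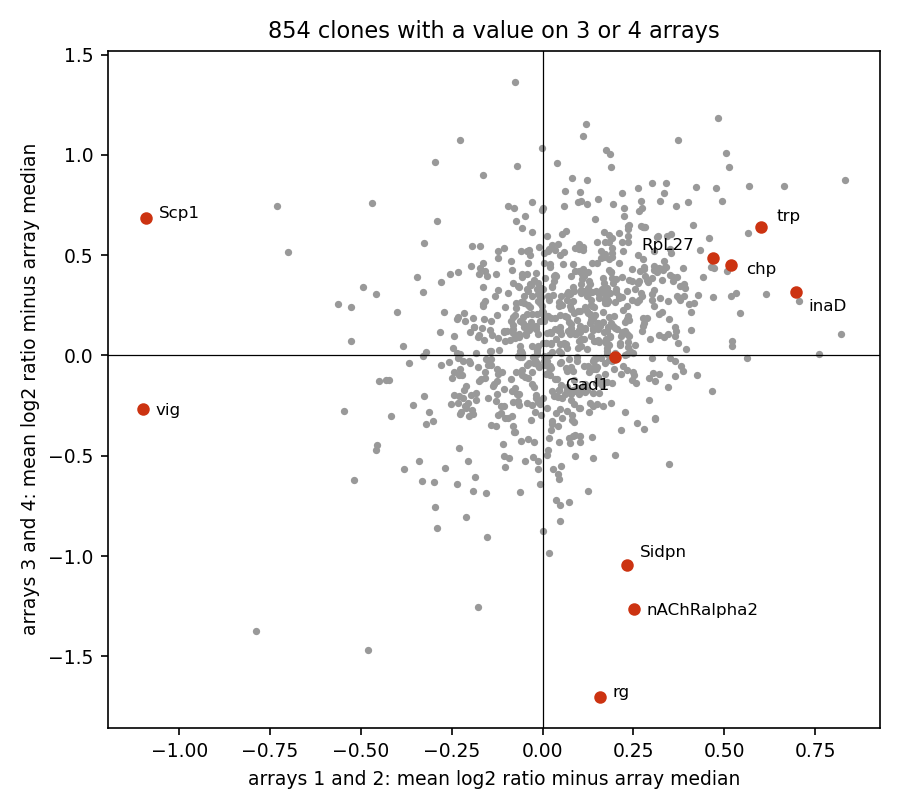
Each point is 1 of 854 clones, by its deposited log2 ratios minus the array median. The horizontal axis is the mean over those of arrays 1 and 2 with a value, and the vertical axis that over arrays 3 and 4. For the 668 clones on 3 arrays, 1 axis shows a single array. This is array 3 on the vertical axis for trp, RpL27 and Scp1, and array 2 on the horizontal axis for rg, nAChRalpha2 and Sidpn. The vig clone with a mean of -0.82 in the text also has no value on array 4. Labelled clones are named in the text; rg, nAChRalpha2 and Sidpn lie low on the vertical axis only, and trp, inaD, chp and RpL27 lie above 0 on both.

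Arrays of 1 orientation run the same way in either reading, so their deviations from the median were also tested alone, a comparison chosen after the data were seen. On arrays 1 and 2, 20 of 1096 clones passed (limma adjusted p under 0.05), 7 above and 13 below the median. Below it lay CG3795 at -1.24 ± 0.20, vig at -1.10 ± 0.19, Scp1 at -1.09 ± 0.21, CG7744, CG9406, htt (huntingtin), CG15395 and UK114, and above it inaD at 0.70 ± 0.18. Some of these means were carried by 1 array: on arrays 1 and 2, htt had -0.12 and -1.42, Scp1 -1.84 and -0.34, CG3795 -0.61 and -1.86, and UK114 -0.94 and -0.43. On arrays 3 and 4, 8 of 235 clones passed, 1 above and 7 below. Below lay rg at -1.70 ± 0.27, nAChRalpha2 at -1.26 ± 0.27, CG1416 at -1.25 ± 0.27, CG6340, Sidpn and Paip1. CG1416 had -0.43 on array 3 and -2.07 on array 4, Paip1 had -1.48 and -0.44, and the SE, which limma moderates over all clones, is the same for each. These calls rest on 2 arrays each, gabapentin and dye cannot be told apart within an orientation, and scaling the arrays to 1 spread left 3 and 0 calls. Of the 11 clones called on arrays 1 and 2 with a value in the other orientation, 8 kept their sign there and 3 did not, and of the 5 called on arrays 3 and 4, 2 did and 3 did not.

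Arrays agreed weakly with one another across clones, which are not independent replicates. As deposited, arrays of the same orientation correlated at r = 0.20 (arrays 1 and 2) and 0.35 (arrays 3 and 4), and arrays of opposite orientation at 0.25, 0.28, 0.26 and 0.09. Over the 186 clones on all arrays, arrays 2 and 4 had r = -0.20, whereas the other 5 pairs stayed above 0.

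Lists with fewer than 5 measured genes had no set test, and in them 0 clones passed over all clones tested after centring in either reading. Of tissue markers, the muscle clones Act79B, Act88F and Mlc2 had a mean of 0.37 ± 0.23 (SD) in the second reading, and 2 passed when adjusted over the list alone, but the mean was -0.19 ± 0.26 in the first. Gs2, the only glia marker tested and also a member of the glutamate list, stood at 0.30 ± 0.13 (SE, n = 4) in the second reading and -0.12 ± 0.17 in the first. apolpp, the only fat body marker tested, ranged from -1.06 to 0.69 relative to the medians of the 4 arrays. In the first reading apolpp and nAChRalpha2, each the only tested clone of its list, passed when adjusted over the list alone, which for 1 clone is the unadjusted p. In the second reading nAChRalpha2 passed in the same way with the opposite sign, at -0.76, and so did Gs2 in the glia list. The gut list had 1 tested clone, at 0.12 in both readings, and no testis or accessory gland gene reached 3 arrays. The glutamate list, with Gdh, Gs2 and Eaat2, had a mean of 0.29 ± 0.14 in the second reading, with 1 passing over the list alone, and -0.07 ± 0.16 in the first. The 6 odorant-binding clones had a mean of 0.13 ± 0.50 and 2 passing over the list alone in the second reading. The 4 cytochrome P450 clones had means of -0.02 ± 0.05 and -0.06 ± 0.21 in the second and first reading.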

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

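The tests in this part on correlations and on clones called within an orientation were chosen after the result was seen; those on matched random lists and on spot pairs were set before their result was seen.

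1 of 31 values examined over the 4 arrays stood apart from the rest, and chance gives about 1 in 20. Spots with a value were split in row order, taken as the printing order, into 3 equal parts. From the first to the last part the median log2 ratio changed by 0.304 on array 2, against -0.18 to -0.15 on the other arrays.

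Array columns correlated above 0 across dye orientations, with photoreceptor and ribosomal protein clones above the medians in both. Gabapentin as the main shared source with values left as Cy5 over Cy3 would give correlations below 0 between orientations, and their mean was 0.221, although arrays 2 and 4 had -0.20 over clones on all arrays. A drug effect in values that the authors had already turned and a dye bias of each clone that recurs on every array both need equal correlations within and across orientations. The observed difference was 0.0549 against an SD of 0.0854 of the 6 correlations, but it was 0.17 without replicate 1, 0.088 with the printing trend removed and -0.052 without replicate 4. These explanations cannot be told apart, because the labels leave the direction open, both predict the same columns and the difference depends on single arrays.

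The list shift itself was set against clones that passed the spot filter on the same arrays. In 10000 random lists matched on the arrays with a value, the median list mean was 0.09 for both. The photoreceptor clones had 0.30 and the ribosomal protein clones 0.31, which 0.18% and 0.13% of the random lists reached. The lists were chosen for lying above the same clones, so small shares were built in, and random lists treat clones as independent. These shares therefore add no evidence for the shift itself, which had an adjusted p of 0.435 with an estimated correlation. They also cannot decide whether the set of arrays with a value is its source. Muscle markers (mean 0.37) and the glutamate list (0.29), with 3 clones each, lay as high in the same reading and were too small for a list test. A drug effect on these genes, their dye bias or the set of arrays with a value may stand behind the shift, and each stays open as a hypothesis.

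The clones called on arrays 3 and 4 alone, include rg, nAChRalpha2, CG1416 and Sidpn. In 8 of 8 called clones both spots lay on the called side on both arrays, whereas this held for 18 of the 20 clones called on arrays 1 and 2. This argues against pairs with spots on opposite sides of the median. The check took the side and not the size, so 1 outlying spot of a pair is not excluded. For the 5 with a value on arrays 1 and 2, the mean there in the called direction was -0.0328, against a mean size of 1.22 where they were called, but 3 of them had a value on array 2 only. A gabapentin effect in either reading and an array or dye effect cannot be told apart on so few arrays.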

How the results depend on the processing

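Chosen after the data were seen were cameraPR and the use of arrays 1 to 3 for the lists, although the settings of the first reading and the uncentred second reading had been planned for camera, and also centring combined with the second reading or with any further choice (a replicate left out, array weights, SAM, complete clones), SAM in the second reading, the settings within an orientation, and those with the printing trend removed; the others were planned. No paired analysis was possible because every array already pairs both conditions and there is only 1 group. Where no cause is given for a changed value, the cause was not tested. Signal over background was 1 of the criteria of the authors' filter, which left 854 of 13824 clones to test, and the losses were not split by criterion.

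The count of 0 higher and 0 lower clones held in 26 of 33 alternatives. Many of the 26 were uncentred with arrays 3 and 4 turned, where limma recovered 7% of simulated changes of 1 unit. A count of 0 says little there. The count became 833 higher with values taken as already turned (796 with SAM) and 754 higher with array weights, all uncentred, so that offsets of the arrays count as change. With weights and centring together it was 0. After centring, without replicate 1 it was 4 higher in the first reading (rg at adjusted p = 2.78e-05, nAChRalpha2, CG1416 and Sidpn) and 1 lower in the second (rg, 0.00937), over 211 clones, so rg was called in opposite directions by the reading. rg, nAChRalpha2 and Sidpn had no value on array 1, so their means of 1.19, 0.93 and 0.77 in the first reading stayed the same. For these 3 only the tested set and limma's moderation changed, so their calls say nothing of array 1. CG1416 had -0.42 on array 1, against the direction of its mean of 0.86 without that array, so its call does depend on leaving it out. The SE was 0.221 for each of the 4 clones. Scaling or robust moderation in the second reading gave 1 lower, the same unnamed clone. The 185 clones of the common component fell to 0 with centring or with scaling and ranged from 183 to 730 when a replicate was left out, more clones being complete without array 4. Those of the opposite component ranged from 0 to 1. The mean correlation within orientations less that across them was 0.17 without replicate 1, 0.088 with the printing trend removed and -0.052 without replicate 4, against an SD of 0.0854. Within arrays 1 and 2, 20 calls became 1060 uncentred, 3 scaled and 50 without the printing trend, and within arrays 3 and 4, 8 became 164 uncentred and 0 scaled.

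Of the gene lists, none passed in the first reading. Relative to the main adjusted p of 0.975, glycolysis turned from higher to lower, and oxidative phosphorylation from lower to higher, with 0.956 after centring for each, 0.776 and 0.703 in the second reading uncentred, 0.743 for each there after centring, and 0.947 and 0.607 for each with an estimated correlation and with fry on arrays 1 to 3. Oxidative phosphorylation also turned with a dye term (0.902) and without replicate 1, 3 or 4, and lay between 0.705 and 0.887 without a replicate; glycolysis also turned without replicate 4 (0.837). Translation factors turned with gene averages (0.961).

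Photoreceptor genes turned to lower with ranks (0.931) or without replicate 2, and ranged from 0.185 to 0.739 without a replicate; ribosomal proteins turned with a dye term (0.902) or without replicate 1 or 2, and ranged from 0.705 to 0.837. Both passed only as higher in the second reading: uncentred 0.0136 and 0.0205, centred 0.0186 and 0.00881, with gene averages 0.0168 and 0.00608, without the printing trend 0.035 and 0.0169, scaled 0.0233 and 0.0129, and without replicate 4 0.0025 and 0.00422. Photoreceptor genes also passed there with a dye term (0.0231) and without replicate 1 (0.0372), and ribosomal proteins with ranks (0.0049). The calls there were lost for photoreceptor genes with ranks (0.0509) and without replicate 2 or 3, for ribosomal proteins with a dye term (0.283) and without replicate 1, 2 or 3, and for both with an estimated correlation (0.435). Tested by fry against no change, a different question, both had 0.116. The photoreceptor list passed in 8 of 23 settings, fry included, and the ribosomal protein list in 7 of 23.

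Of 280 alternative values for 23 named clones, 251 kept direction and side of the threshold, 13 passed only without centring and 3 only without replicate 1. These 3 were rg, nAChRalpha2 and Sidpn, which had no value on array 1 and kept their means. With the other reading, the sign turned for nAChRalpha2 (-0.76), rg (-1.08), Sidpn (-0.62) and CG2233 (0.13), and for CG10553 (-0.065), thoc7 (-0.048), CG4716 (-0.31), RpL39 (-0.13), RpL15 (-0.064) and Obp56g (0.17), by the turning itself. Without centring it turned for CG16926 (0.011), CG4757 (0.064) and Obp56g (0.010), by the offset of the arrays.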

Other observations

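The comparison in this part was chosen after the data were seen. The share of genes with values on 3 or 4 arrays differed between gene groups. Of 17 photoreceptor genes on the array, 8 (47.1%) had a value on 3 or 4 arrays, against 6.18% of the other 6776 named genes (Fisher's exact test, adjusted p = 0.000111 over 33 lists). The measured genes were trp, trpl, inaC, inaD, chp, Galphaq, rdgC and CG2233. Glycolysis followed with 6 of 13 genes (46.2%, adjusted p = 0.00115), ribosomal proteins with 7 of 23 (30.4%, adjusted p = 0.00309) and oxidative phosphorylation with 10 of 43 (23.3%, adjusted p = 0.00279).

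In 5 of these 33 lists no gene reached 3 arrays, but the test did not separate them from the rest. They were cuticle with 51 genes (adjusted p = 0.206 by Fisher's exact test) and testis with 13, oxidative stress with 13, circadian rhythm with 8 and accessory gland with 5, each at an adjusted p of 1. Mitochondrial ribosomal proteins had 1 of 48 and cytochrome P450 genes 4 of 72, with adjusted p of 0.637 and 1. No list passed the test in the lower direction. All 4 arrays went through the same spot filter, so these counts describe which spots passed, and genes were treated as independent.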
